A study of Homo sapiens with 6 samples.

How the data were processed

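Messenger RNA was measured in 6 libraries of HTR8/SVneo cells, 3 transfected with scrambled control siRNA and 3 with GATA3 siRNA, each at 50 nM and labelled 48 h. Per the labels' protocols, 1 siRNA product was used per group, RNA was taken after transfection with a lipid reagent, and poly(A)-selecting, strand-keeping libraries were sequenced from a single end. Per the submitters' processing notes, STAR 2.2.1, RSEM 1.2.20, DESeq2 1.10.1 and R 3.2.2 were used with the genome build GRCh38. The annotation, read filters and strand setting were not given in the sources used here. The authors deposited 1 table of estimated counts per gene (RSEM expected counts), not scaled for library size, with 1 column per library. Of its 27791 rows, 27699 were genes and 92 were synthetic spike-in RNAs. The spike-in rows held 17 counts in all and stayed out of library sizes and tests.

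Expected counts were rounded to whole numbers before testing. Gene symbols were those of the table. Coordinates and gene types came from GENCODE release 29 on GRCh38, where 27162 gene IDs were found and 537 were not. A symbol shared with another row occurred in 223 gene rows, and results are given per gene ID. Because the strand setting of the counting was not stated, overlapping genes, readthrough genes and near-identical family members are treated as uncertain.

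Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total count 15, at least 3 libraries), which left 13900. Libraries were scaled by TMM, with factors from 0.964 to 1.03. The main test was edgeR's quasi-likelihood F test of GATA3 siRNA against control with group as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. The common dispersion was 0.00129, a biological coefficient of variation of 3.59%. Standard errors of log2 fold changes were taken from the F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Totals from 13105723 to 48225197 counts per library mean that counting error is small for abundant genes and large for genes near the filter. The labels mention no molecular identifiers; if PCR copies were counted, counting error understates the error of a single library. Replicates of a group differed by more than counting noise (chi-square over degrees of freedom from 2.07 to 6.33), so none were treated as duplicates.

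The gene test was tested on simulated data with the real means, library sizes and dispersion (10 simulations of 13900 genes, 200 of them changed). It recovered 67.4% of genes changed 1.25-fold, 80.1% of those changed 1.5-fold and 93.2% of those changed 2-fold. Unchanged genes made up 8.8% of the calls, above the nominal 5% share implied by the threshold of 0.05. The list test called a raised list of 30 genes in 10 of 10 simulations and an unchanged list in 0, at an unadjusted camera p under 0.05. Genes were simulated independently and all 30 raised members changed 1.5-fold, so lists of correlated genes or smaller shifts were not checked. With 200 genes changed per simulation, against 5892 called in the data, the recovery and error shares may differ there.

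Before the data were examined, 32 gene lists, the design, the rule for named genes and the main alternatives were fixed. Lists covered trophoblast lineages, matrix, proteases, signaling pathways, cell cycle, stress, metabolism and markers of stromal, endothelial and blood cells; several lists share members, and GATA3 was in none. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, then with an estimated correlation and with fry. The rule named GATA3, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM whose groups do not overlap, then the 5 smallest p in each direction, then up to 3 called members per list with the largest fold change. Further list members in the text, such as IL6, JUN, PTPN14, TNS1, MCM6, MDM2, FN1, CDKN1C, TFAP2A, GATA2, VEGFA and LDHA, were chosen after their values were seen.

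Alternatives were DESeq2 1.42.0, limma-voom, robust dispersion, RLE, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library and a fold threshold of 1.5. Thinning to equal depth, leaving out genes with ATATTA or GACGTA in the 3′ UTR and removing a trend with length and expression were added after seeing the data. The plan for the 3′ UTR search named only genes that fell. For the 3′ UTR search, 12800 tested genes with an annotated 3′ UTR of at least 50 bases in the GENCODE basic set were stratified into 10 bins of UTR length and 5 of expression, and each of 15962 7-base sequences present in at least 100 genes was tested for excess among the genes that fell (2951) or rose (2687). With shuffled calls 0 of the 2821 searched sequences found in GATA3 transcripts were called, and a planted sequence ranked 1 among all searched. A single shuffle and a single planted strength were used, so the recovery of weaker excesses was not checked. Each called list was also tested among genes with a searched 3′ UTR and no site, and with the trend fitted without its own members, with standard errors of medians from resampling of members. Figures were drawn with matplotlib 3.10.9, and the 3′ UTR search used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.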

Results

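RNA sequencing was done on HTR8/SVneo cells, an immortalized human trophoblast line derived from early placenta, after transfection with a small interfering RNA (siRNA) against GATA3 or with a scrambled control siRNA. GATA3 is a zinc-finger transcription factor expressed in trophoblast. Each group held 3 libraries, all labelled with 48 h and transfected with 50 nM siRNA. The deposited table gave estimated read counts per gene. Library totals were 31777812, 35222170 and 13105723 counts for control replicates 1, 2 and 3, and 16897275, 20577891 and 48225197 for GATA3 siRNA replicates 1, 2 and 3. The largest total was 3.68 times the smallest. The mitochondrially encoded share of counts was 7.99%, 7.35% and 7.20% in the controls and 6.81%, 7.01% and 6.92% with GATA3 siRNA. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

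The targeted gene was examined in each library to check the labels. GATA3 (ENSG00000107485, chromosome 10, 8045378 to 8075203, plus strand, GRCh38) was present at 57.9, 54.9 and 58.6 CPM (library-scaled counts) in the control libraries and at 29.3, 24.2 and 24.4 CPM in the GATA3 siRNA libraries, from 506 to 1888 counts per library. The mean was 57.1 ± 1.94 CPM in controls and 26.0 ± 2.88 CPM with GATA3 siRNA (SD, n = 3 each). The siRNA group therefore kept 45.5% of the control level. The log2 fold change was -1.15 (SE 0.06), with an adjusted p of 6.78e-10 in edgeR's quasi-likelihood test. An exact two-sided permutation test of the CPM values gave p = 0.1, the smallest that 20 relabellings of 3 against 3 libraries allow. Every library matched its label in this gene.

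The comparison of GATA3 siRNA with control siRNA asked which genes lie downstream of GATA3 in trophoblast cells. After knockdown, the genes with the strongest evidence of a fall included the matricellular growth regulators CYR61 and CTGF, the cyclin CCND1, the apoptosis inhibitor BIRC3 and the protein crosslinking enzyme TGM2. The genes with the strongest evidence of a rise included the antiproliferative gene BTG2, the cyclin-dependent kinase inhibitor CDKN1A, the DNA damage recognition gene DDB2 and the cell cycle transcription factor E2F2. CYR61 went from 529 ± 7.59 to 250 ± 6.98 CPM, CTGF from 54.9 ± 2.92 to 20.1 ± 0.695 CPM and CCND1 from 59.9 ± 1.28 to 21.2 ± 1.96 CPM (mean ± SD, n = 3 each). CDKN1A went from 232 ± 13.8 to 410 ± 22.7 CPM and E2F2 from a mean of 27.8 to 50.8 CPM, and BTG2 rose 2.012-fold.

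**Figure D1:**
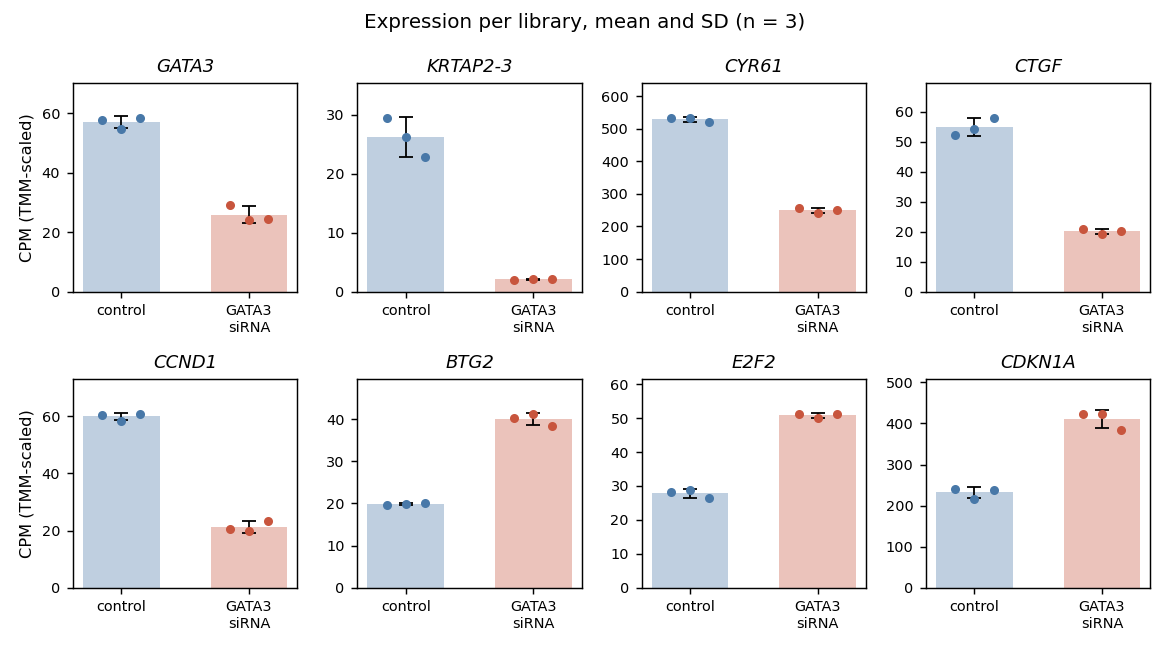
Expression in TMM-scaled CPM of 8 genes in the control siRNA libraries (blue) and the GATA3 siRNA libraries (red). Points are single libraries, bars are means and error bars are SD (n = 3 each); for each gene shown, the libraries of 1 group lie apart from those of the other, as for GATA3 with means of 57.1 and 26.0 CPM.

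Among 13900 genes tested, 5892 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, which was 42.4% of them. Of these, 2801 rose and 3091 fell. Most of the changes were small, with a median fold of 1.204. At least 1.5-fold changes were found for 482 genes that rose and 246 that fell, and at least 2-fold changes for 135 that rose and 70 that fell. The groups did not overlap for 7140 genes (51.4% of those tested), against 10% from chance with 3 libraries per group. The first principal component held 50.3% of the variance and separated the groups. On the second (17.9%), control replicate 3 lay at -21.76 and the other controls at 11.96 and 13.12. Relative to each gene's mean, the slope of log2 expression on log2 transcript length ran from -0.0403 to -0.0093 in controls. With GATA3 siRNA it ran from 0.021 to 0.024. The split of calls depended on scaling. With library totals alone, 4572 genes rose and 1864 fell, and with upper-quartile scaling 3478 rose and 2515 fell, so that the share of rises was 47.5% in the main test, 71% and 58%.

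**Figure D2:**
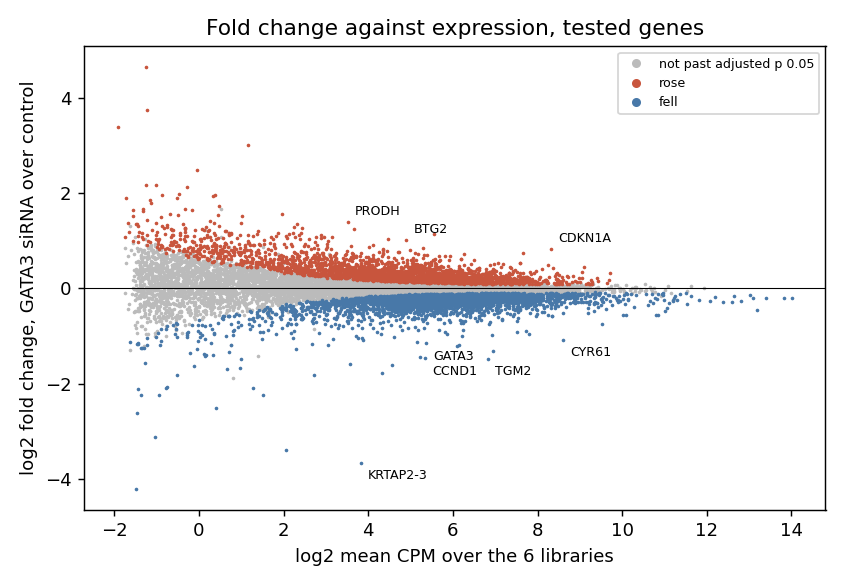
Log2 fold change of GATA3 siRNA over control against log2 mean CPM over the 6 libraries, with 1 point for each of the 13900 tested genes. Genes that rose (red, 2801) and fell (blue, 3091) at an adjusted p under 0.05 lie mostly close to 0, and KRTAP2-3 stands out among the falls with a log2 fold change of -3.66.

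The largest fall by the fixed rule was in the keratin-associated protein gene KRTAP2-3 (ENSG00000212724, chromosome 17, 41059240 to 41060114), which went from 26.2 ± 3.36 to 2.08 ± 0.0543 CPM (log2 fold change -3.66, SE 0.11, edgeR adjusted p = 9.37e-13). Its family holds near-identical copies, so its level is uncertain. The next falls were in TNFRSF6B, a decoy receptor of the tumor necrosis factor family, at a log2 fold change of -2.25, the basal keratin KRT15 at -2.08, the muscle ankyrin repeat gene ANKRD1 at -1.81, the lipolysis inhibitor G0S2 at -1.78 and the insulin-like growth factor binding protein IGFBP5 at -1.69. TNFRSF6B overlaps a readthrough gene, RTEL1-TNFRSF6B, whose log2 fold change was 0.32, and its counts are uncertain for that reason. The noncoding RNA LINC00460, the gastrin-releasing peptide receptor GRPR, the G protein regulator RGS4 and TGM2 fell with log2 fold changes from -1.67 to -1.48. The falls with the smallest p outside these were in CYR61 (-1.08), BIRC3 (-1.22), CTGF (-1.44), the transcription elongation factor TCEA1 (-0.89) and CCND1 (-1.47). The 3′ UTRs of TCEA1, CTGF, CCND1 and IGFBP5 carried all or 7 bases of the sequence AATATTAA. These were 4 of the 14 searched falls named by these rules, against 3765 of all 12800 searched genes. Of all searched falls of at least 1.5-fold, 74 of 204 carried such a site. Over all genes, those with such a site fell more often than matched genes (979 observed, 683.5 expected).

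The largest rise by the same rule was in CORO7-PAM16, a readthrough of 2 neighboring genes, with 38, 0 and 0 counts in the controls and 38, 148 and 144 with GATA3 siRNA. It shares reads with CORO7 and PAM16 and was not called by DESeq2 (adjusted p = 0.257). The next were USH1G at a log2 fold change of 1.96, the noncoding RNA LINC01554 at 1.94, C15orf59 at 1.74, the inositol phosphatase INPP5D at 1.56 and the adhesion adaptor SORBS1 at 1.52. SPSB4, PVRL4 (a nectin adhesion molecule) and GREB1 rose with log2 fold changes from 1.37 to 1.41 at low levels, with means over all libraries from 1.19 to 1.98 CPM. PRODH, the proline dehydrogenase, rose from 6.32 ± 0.16 to 16.5 ± 0.348 CPM (log2 fold change 1.39, SE 0.08, edgeR adjusted p = 1.14e-09). The rises with the smallest p outside these were in BTG2 (1.01), CORO6 (1.03), E2F2 (0.86), CDKN1A (0.82) and DDB2 (0.69). The 3′ UTRs of USH1G, CORO6 and E2F2 carried the sequence GACGTA. These were 3 of the 14 searched rises named by these rules, against 592 of all 12800 searched genes. Over all genes, those with it rose more often than matched genes (235 observed, 140.2 expected). Of the genes named from lists, JAG1 and DTX4 rose and KISS1 and GATAD2A fell with this sequence. INPP5D rose although its 3′ UTR carried all 8 bases of AATATTAA.

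Gene lists fixed before the data were examined were then compared with all other genes by camera with a preset correlation. Of 32 lists, 13 were called as lower and 2 as higher at an adjusted p under 0.05, and none with a correlation estimated from these libraries, where 9 had an unadjusted p under 0.05. Genes controlled by the Hippo pathway cofactors YAP and TAZ fell together: 16 of 27 measured members fell, 4 rose and 7 did not pass. ANKRD1, CTGF and CYR61 fell most, while the phosphatase PTPN14 (0.48) and the cytoskeletal gene TNS1 (0.36) rose. The list's adjusted p was 7.98e-07 (camera), and the adjusted p was 0.0599 with an estimated correlation. Inflammatory cytokines and NF-kB targets also fell, with 16 of 28 members lower and 2 higher. BIRC3, the pattern recognition protein PTX3 (-1.13), the cytokine IL11 (-0.91) and IL6 (-0.84) were among them. This list's adjusted p was 3.07e-08 (camera) and the adjusted p was 0.0557 with an estimated correlation. Immediate early and heat shock genes gave 18 of 36 members lower and 3 higher, with an adjusted p of 3.2e-05 (camera) and an adjusted p of 0.0557 with an estimated correlation. MYC went from 296 ± 10.4 to 151 ± 4.86 CPM, FOSL1 fell by 0.91 and JUN by 0.66 on the log2 scale, and BTG2 rose. Adjusted over the list alone, 17 YAP and TAZ targets fell and 5 rose, the inflammatory counts did not move, and 19 immediate early and heat shock genes fell.

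The 2 lists called as higher were p53 targets and S phase genes. Of 35 p53 targets, 23 rose, 3 fell and 9 did not pass. BTG2, CDKN1A and the quinone oxidoreductase gene TP53I3 (0.71) rose most, the p53 ubiquitin ligase MDM2 rose from 154 ± 2.92 to 200 ± 4.88 CPM, and GADD45A, RRM2B and PLK2 fell. For p53 targets the adjusted p was 3.07e-08 (camera) and the adjusted p was 0.0557 with an estimated correlation. Of 54 S phase genes, 30 rose, 5 fell and 19 did not pass. E2F8 (0.60), WDR76 (0.46) and the cyclin CCNE1 (0.46) rose most, and the replication helicase subunit MCM6 rose by 0.36 on the log2 scale. For S phase genes the adjusted p was 2.56e-06 (camera) and the adjusted p was 0.139 with an estimated correlation. Adjusted over the list alone, 24 p53 targets rose and 5 fell, and 31 S phase genes rose and 5 fell. The 63 genes of the G2 and M phases were not called, with 14 higher, 10 lower and an adjusted p of 0.63 (camera). Among them RANGAP1 and CKS1B fell by 0.43 and 0.32 and the proliferation marker MKI67 rose by 0.29.

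Of the lists tied to trophoblast identity and invasion, camera (preset correlation) called extravillous trophoblast genes, trophoblast transcription factors and protease inhibitors as lower. The others, given further below, were not called by it. Fry also called syncytiotrophoblast genes (adjusted p = 0.0057), matrix-degrading proteases (0.00168) and epithelial genes (0.0249) as lower. Of 40 listed extravillous trophoblast genes, written as markers of the invasive lineage, 29 passed the filter, and HLA-G, PAPPA2, ASCL2 and LAIR2 did not. Of the 29 measured, 15 fell and 5 rose. Several that fell, among them TIMP3, ADAM19 and FN1, also stand in the protease, protease inhibitor or matrix lists. PLAC8, the metalloprotease ADAM19 and the protease inhibitor TIMP3 fell with log2 fold changes of -0.87, -0.73 and -0.69, fibronectin (FN1) fell from 848 ± 9.68 to 726 ± 43.5 CPM, and CDKN1C rose by 0.61. The list's adjusted p was 0.000187 (camera) and the adjusted p was 0.0557 with an estimated correlation. Of 27 trophoblast transcription factors, 10 fell and 4 rose. FOSL1 and TFAP2A fell, the latter from 213 ± 7.09 to 157 ± 1.96 CPM, while EOMES and DLX4 rose by 0.77 and 0.59, and GATA2 did not pass at an adjusted p of 0.0846 (edgeR). The factors' adjusted p was 0.0379 (camera) and the adjusted p was 0.2025 with an estimated correlation, and the list's median of -0.08 became 0.0023 with library totals alone, which moved the median of all genes by 0.0796 and left the call in place (0.0336). Protease inhibitors gave 9 of 21 lower and 3 higher, led by SERPINB7, TFPI2 and TIMP3, with an adjusted p of 0.0379 (camera) and an adjusted p of 0.191 with an estimated correlation. The transcription factor call ended with limma-voom (0.103), without control replicate 3 (0.115) and without GATA3 siRNA replicate 1, 2 or 3 (0.0608, 0.0597 and 0.0575), without genes carrying ATATTA or GACGTA in the 3′ UTR (0.167, median -0.07) and with a trend of the fold change with transcript length and expression removed (0.0728, median -0.09), the median staying near -0.08. The protease inhibitor call ended with limma-voom (0.139), without control replicate 1 or 2 (0.0522 and 0.0526) and with the trend removed (0.14). Without the site genes the protease inhibitor median turned from -0.08 to 0.0266 (adjusted p = 0.644). Adjusted over the list alone, 11 transcription factors fell and 4 rose, and the other counts did not move.

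**Figure D3:**
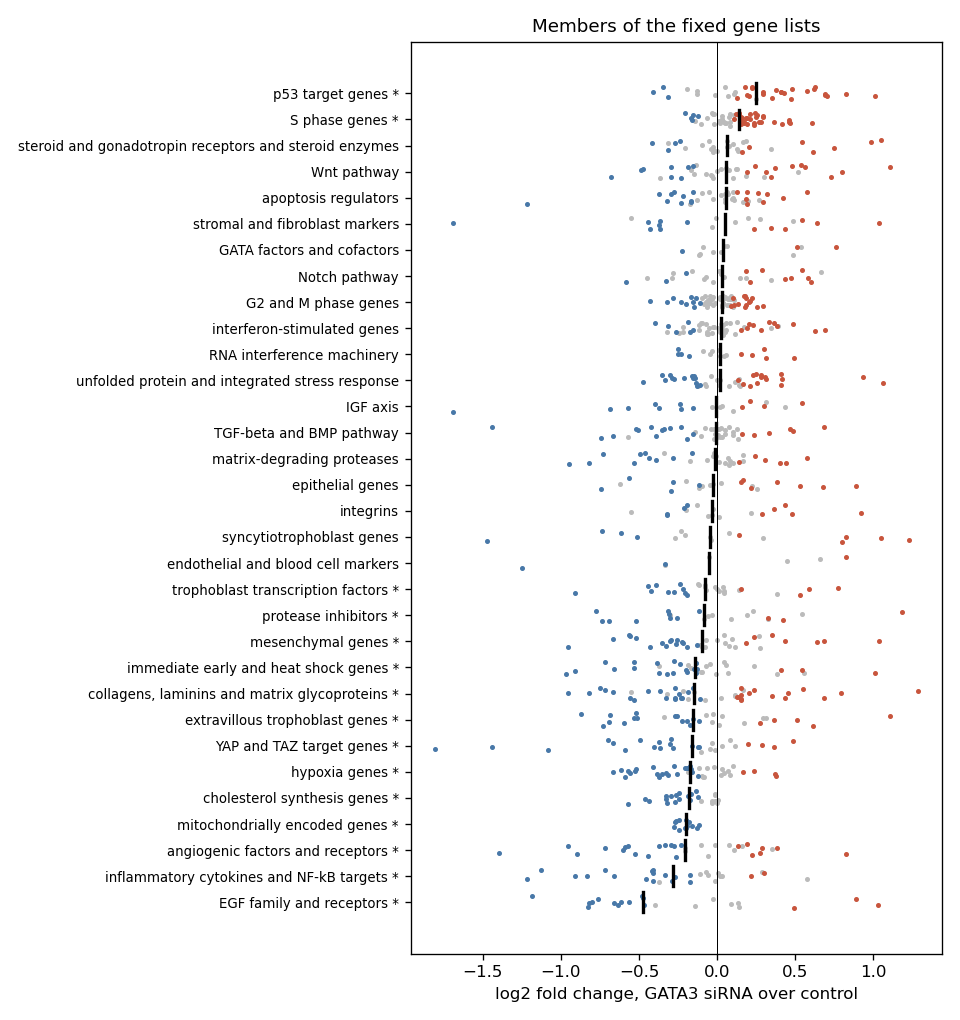
Log2 fold change of GATA3 siRNA over control for each measured member of the 32 fixed gene lists, with red points for genes that rose, blue for genes that fell, grey for genes that did not pass and black bars for list medians. Stars mark the 15 lists called by camera with a preset correlation; p53 targets had the highest median (0.25) and the EGF family list the lowest (-0.47).

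Matrix and mesenchymal genes moved in both directions. Of 44 collagens, laminins and matrix glycoproteins, 19 fell and 15 rose, with an adjusted p of 0.0134 (camera) and an adjusted p of 0.436 with an estimated correlation. The fibrillar collagen gene COL5A3 rose by 1.28 and the laminin chain LAMB3 and thrombospondin THBS1 fell by 0.82 and 0.96 on the log2 scale. The matrix call ended with limma-voom (0.156), without GATA3 siRNA replicate 3 (0.0534), without the site genes (0.0944) and with the trend removed (0.0728), while the median of -0.15 became -0.15 and -0.16 in the last 2. Of 35 mesenchymal genes, 16 fell, THBS1 and the lysyl oxidase LOX the most, and 7 rose, PDGFRA and the matrix glycoprotein tenascin C (TNC) the most. For mesenchymal genes the adjusted p was 0.000532 (camera) and the adjusted p was 0.156 with an estimated correlation, and it was 0.0675 with the trend removed, where the median of -0.09 became -0.10. Of 31 angiogenic factors and receptors, 15 fell and 7 rose. The vasoconstrictor peptide gene EDN1 fell by 1.40, FGF1 by 0.89 and VEGFA by 0.37 on the log2 scale. The angiogenic list's adjusted p was 8.25e-05 (camera) and the adjusted p was 0.0557 with an estimated correlation, and it was 0.127 once genes with ATATTA or GACGTA in the 3′ UTR were left out. The list named for the EGF family gave 12 of 21 lower and 3 higher. Its largest falls were in negative regulators of ERK signaling, the phosphatases DUSP6 (-1.19) and DUSP5 (-0.83) and the inhibitor SPRY2 (-0.82), while the receptors ERBB3 and ERBB4 and the ligand TGFA rose. The adjusted p was 1.19e-05 (camera) and the adjusted p was 0.2025 with an estimated correlation, and it was 0.117 without the same genes. Adjusted over the list alone, 20 matrix genes fell and 16 rose, 12 genes of the EGF list fell and 5 rose, and the other counts did not move.

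Metabolic lists were lower as well. None of 24 cholesterol synthesis genes rose and 16 fell, among them DHCR7 (-0.57), MVD (-0.46) and the sterol sensor INSIG1 (-0.44). Their adjusted p was 2.2e-06 (camera) and the adjusted p was 0.0557 with an estimated correlation. Of 39 hypoxia genes, many of which encode glycolytic enzymes, 22 fell and 4 rose. LOX, the glucose transporter SLC2A1 and ANGPTL4 fell by 0.66, 0.61 and 0.59 on the log2 scale, and the lactate dehydrogenase LDHA went from 2122 to 1445 CPM. For hypoxia genes the adjusted p was 7.2e-07 (camera) and the adjusted p was 0.233 with an estimated correlation. All 13 mitochondrially encoded messages fell, MT-ND2, MT-ND4L and MT-CO3 the most, with log2 fold changes of -0.28 to -0.26. Their adjusted p was 0.000187 (camera) and the adjusted p was 0.456 with an estimated correlation. The mitochondrial median was -0.20, and 0.0158 once the trend was removed. Adjusted over the list alone, these 3 lists kept their counts.

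The other lists were not called by camera. Markers of cell types that could contaminate a culture went both ways: of 20 stromal and fibroblast markers 6 rose and 7 fell (adjusted p = 0.63), and of 7 measured endothelial and blood cell markers 1 rose and 2 fell (adjusted p = 0.803). IGFBP5, PDGFRA and ACTA2 led the stromal list and TEK and TIE1 were the called endothelial genes above 1 CPM. Of 16 syncytiotrophoblast genes 5 rose and 4 fell (adjusted p = 0.338), with KISS1 and TFPI2 lower by 1.47 and 0.74 and HSD11B2 higher by 1.05. Of 30 matrix-degrading proteases 6 rose and 10 fell (adjusted p = 0.17), with the urokinase receptor PLAUR lower by 0.95, ADAMTS12 by 0.82 and ADAM19 by 0.73. Of 17 integrins 5 rose and 4 fell (adjusted p = 0.915), with ITGB3, ITGB4 and ITGA7 higher and ITGA3 (721 to 577 CPM), ITGA5, ITGB5 and ITGA2 lower. Of 21 epithelial genes 7 rose and 5 fell (adjusted p = 0.338), with KRT18 and KRT8 lower by 0.74 and 0.57 and KRT17 and TJP3 higher at low levels. Of 12 GATA factors and cofactors 2 rose, GATA5 and FOXA1, and 1 fell, GATAD2A (adjusted p = 0.812).

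Signaling lists outside those called by camera gave smaller or mixed movements. By fry, the TGF-beta and BMP pathway (adjusted p = 0.00273), the insulin-like growth factor axis (0.00299) and apoptosis regulators (0.0114) were called as lower. The Notch pathway was called as higher by fry (adjusted p = 0.00299). The TGF-beta and BMP pathway had 6 of 42 members higher and 13 lower (camera adjusted p = 0.0915), with CTGF and BMP6 lower and LTBP1 higher. The insulin-like growth factor axis had 4 of 18 higher and 8 lower (adjusted p = 0.2), with IGFBP5, PAPPA and STC2 lower. The Notch pathway had 8 of 26 higher and 3 lower (adjusted p = 0.206), with JAG1 and DTX4 higher and NRARP lower. The Wnt pathway had 11 of 37 higher and 8 lower (adjusted p = 0.891), with ROR2 and WNT9A higher and SFRP1 lower. Steroid receptors and enzymes had 7 of 30 higher and 4 lower (adjusted p = 0.63), with HSD11B2, PAQR8 and GPER1 higher. Interferon-stimulated genes had 11 of 51 higher and 6 lower (adjusted p = 0.63), with GBP2, TRIM22 and SAMD9L higher. Apoptosis regulators had 9 of 38 higher and 10 lower (adjusted p = 0.63), with BIRC3 lower and FAS and BMF higher. The unfolded protein and integrated stress response had 15 of 41 higher and 14 lower (adjusted p = 0.63), with ALDH1L2 and CHAC1 higher and XBP1 lower. The RNA interference machinery had 5 of 16 higher and 4 lower (adjusted p = 0.891), with TLR3, AGO4 and TNRC6C higher.

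Median, mean and test differed in sign for some of these lists. Syncytiotrophoblast and epithelial genes had medians of -0.04 and -0.03, means of 0.02 for both, and a test direction of lower. Integrins had a median of -0.03, a mean of 0.04 and a test direction of higher. Stromal markers had a median of 0.05, a mean of -0.0075 and a test direction of lower, and apoptosis regulators a median of 0.06 and a test direction of lower. Adjusted over the list alone, 10 interferon-stimulated genes rose and 5 fell, 9 apoptosis regulators rose and 12 fell, 17 stress response genes rose and 15 fell, 7 TGF-beta genes rose and 13 fell, 6 steroid genes rose and 4 fell, 5 genes of the insulin-like growth factor axis rose and 8 fell, and 5 integrins rose and 5 fell, with no other change. The calls of ANGPTL4, EOMES, GBP2, GPER1, ITGB3, JAG1, KRT17, PDGFRA, SERPINB7, TEK, TJP3, TLR3, TNRC6C and WNT9A ended in at least 1 of 16 alternative settings, with the same direction in all of them.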

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

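No tests in this part were chosen after its result was seen. The synthetic spike-in rows, which no comparison used, held 17 counts, all in control replicate 3 and 0 in each of the other 5 libraries. This was flagged as a signal in data outside the main measurement, because 17 is above the 3 counts that a count of 0 allows. It was 17 of 13105723 counts in that library, and no explanation for it was tested.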

How the results depend on the processing

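Thinning to equal depth, leaving out genes with a 3′ UTR sequence and removing the length and expression trend were chosen after the results were seen; the other settings were planned. The count of changed genes stayed within 1.5 times the main count of 5892 in every alternative test, scaling, filter and left-out library: DESeq2 called 4742, limma-voom 5986, robust dispersion 6020, RLE scaling 5885, no filter 6087, the 1 CPM filter 5861 and thinning 4821. Leaving out 1 library gave 4624 to 5684. Genes called in both the main test and an alternative had the same direction in each of them (4724 shared with DESeq2). Requiring a fold of at least 1.5 left 728 genes, 482 higher and 246 lower, because most changes were smaller. With library totals alone 4572 rose and 1864 fell, because the median log2 fold change of all genes moved by 0.0796. GATA3 kept its call in all alternatives. Of 106 other named genes 91 kept theirs in all 16 alternatives and 15 lost it in at least 1, and none changed direction. Besides the 14 named with the results, this was CORO7-PAM16, with an adjusted p of 0.257 at most. Whether the replicate numbers mark a pairing was not settled: same-numbered libraries had weakly correlated deviations of 0.068, 0.061 and 0.008. Control replicates 1 and 2 correlated best with their own number, and control replicate 3 with GATA3 siRNA replicate 2 (0.02). With the replicate block 5974 genes were called and all 15 lists kept their calls. Of 32 lists, 29 kept their side of the threshold in 16 alternatives. The exceptions were trophoblast transcription factors (11 of 16), protease inhibitors (13) and collagens, laminins and matrix glycoproteins (14). Those 16 left out fry, the estimated correlation, the removal of site genes and the removal of the trend. Without site genes 10 of 15 called lists kept their calls, and with the trend removed 10 of 15. With an estimated correlation 0 lists were called, against 15, the smallest adjusted p being 0.0557, and fry called 22. A stronger correlation between members cannot explain every lost call. The estimate was below the preset 0.01 for transcription factors (0.0069), extravillous trophoblast (-0.0319), protease inhibitors (-0.027), angiogenic (-0.0023), cholesterol (-0.0089) and immediate early genes (0.0058). It was above 0.01 for the other called lists. For extravillous trophoblast genes the unadjusted camera p went from 5.85e-05 to 0.0104 although the estimate was below the preset. Where the estimate was below the preset, a lost call is therefore no evidence of correlation between members. The cause of the difference between the tests was not tested. The mitochondrially encoded list turned to a median of 0.0158 (adjusted p = 0.839) with the trend removed.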

Other observations

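The ribosome biogenesis list, the gene family tests, the list tests without site genes or with the trend removed, and the tests of each called list alone, with their bound, were chosen after the results were seen. The 3′ UTR search among genes that fell was planned, and the search among genes that rose was not. AATATTAA and GACGTA were chosen for closer tests from the sequences that these searches ranked highest. Genes for ribosome assembly in the nucleolus fell together after GATA3 siRNA. In a list of 100 such genes written after the gene test, 85 of 98 measured members fell, 1 rose (the ribosomal DNA transcription factor UBTF, 132 to 158 CPM) and 12 did not pass. The median log2 fold change was -0.34, and -0.26 with library totals alone. NOP16 went from 33.8 to 19.6 CPM, MYBBP1A from 146 to 89.4, RPF2 from 87.9 to 55.7, NOP2 from 102 to 67.5 and BOP1 from 122 to 82.4. With an estimated correlation the camera p was 0.00494, unadjusted and for a list chosen on these data; cholesterol synthesis genes, with an unadjusted p of 0.00482, did not pass once adjusted over the 32 fixed lists. MYBBP1A and RPF2 had been seen among the smallest p before the list was written. The median was -0.29 with the length and expression trend removed, and among 59 members whose searched 3′ UTR held neither ATATTA nor GACGTA it was -0.34. MYC, a known regulator of many of these genes, fell 1.952-fold in the same libraries, and whether that fall precedes theirs was not tested.

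Other families defined by the letters that open the symbol gave smaller movements (82 tested, exploratory). Mitochondrial ribosomal protein genes fell: 31 of 48 MRPL genes were lower and 2 higher (camera adjusted p = 0.000699), and 18 of 30 MRPS genes were lower and 1 higher (adjusted p = 0.00597). Among translation initiation factor genes (EIF) 27 of 53 were lower and 5 higher (adjusted p = 0.00503). Genes opening with POLR, for RNA polymerase subunits, had 14 of 31 lower and 3 higher (adjusted p = 0.021), and those opening with RPS, mostly small-subunit ribosomal proteins, 16 of 42 lower and 2 higher (adjusted p = 0.0255). Zinc finger genes (ZNF) went the other way, with 126 of 461 higher and 34 lower (adjusted p = 0.0109), as did CEP genes of the centrosome, with 14 of 35 higher and 0 lower (adjusted p = 0.0484). Library totals alone moved the median of all genes by 0.0796, and with it the RPS median from -0.07 to 0.0041; the other medians kept their sign. With an estimated correlation no family passed (adjusted p = 0.753 for each of these). Of 614 tested long intergenic noncoding RNAs, 67 rose and 45 fell.

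The count of 5892 changed genes was compared with the other ways to split the 6 libraries into 3 and 3. The real split was the 1 with the most genes and the highest other split gave 0, but 10 splits are too few for a share under 0.05. The other splits mixed libraries of both groups on each side, so any difference between the groups counted there as spread within a side. Their 0 calls therefore carry no weight of their own.

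Genes that fell carried AATATTAA sites in their 3′ UTRs. Of 15962 7-base sequences, AATATTA had the largest excess among genes that fell (z = 10.61, adjusted p = 2.24e-22), followed by ATATTAA (z = 9.33). Against genes matched on UTR length and expression, the log2 shift was -0.10 ± 0.01 (SE) for 1298 genes with all 8 bases. It was -0.05 ± 0.01 for 1373 with AATATTA alone and -0.04 ± 0.01 for 1094 with ATATTAA alone. With the 6-base core it was -0.0008 ± 0.0097 (1239 genes). The highest z of 31 other 7-base sequences of the same bases, sharing no 6-base run with the site, was 3.34. This argues against AU-rich composition alone as the cause. AATATTA was picked as the highest z in the same search, so only the size of that gap carries weight. The shifts come from the same genes as the search. The 8-base shift exceeded that of the core by -0.1014 (SE 0.0149), the order expected of a guide strand acting like a microRNA. The same 8 bases lie in the GATA3 message across the junction of exons 5 and 6 (chromosome 10, from 8069596 to 8073743, GRCh38), before the 3′ UTR. AATATTAT, which holds AATATTA, lies in the GATA3 3′ UTR (8075156 to 8075163). A candidate explanation is therefore a seed effect of the GATA3 siRNA, whose sequence was not given in the sources used here. An excess of 295.5 genes over 683.5 expected is a small part of the 2951 searched genes that fell. Among searched falls of at least 1.5-fold, 74 of 204 carried a 7- or 8-base site, against 3765 of all 12800 searched genes, without matching. KRTAP2-3, CYR61, ANKRD1, TGM2 and GRPR carried none of these sites, while TCEA1, CTGF, CCND1, DUSP6, THBS1 and PLAC8 did.

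Genes that rose carried the sequence GACGTA in their 3′ UTRs. The 592 genes with it lay 0.10 ± 0.01 (SE) above matched genes on the log2 scale, and 235 rose against 140.2 expected. The z of GACGTA was 8.85, and the highest of 57 other sequences of the same bases with 1 CG was 3.3. This argues against its base content alone as the cause. It was picked from the top of the same search, so only the size of that gap carries weight. Of 15962 sequences, 120 passed an adjusted p of 0.05 in that search among genes that rose, against 3 among genes that fell. Some do not hold GACGTA, such as GCCAAAG (z = 5.34) and GGAGGGC (z = 5.11), so a wider difference in 3′ UTR composition stays open. A seed effect of the control siRNA, which would lower these genes in the controls, may be the cause and stays open: the shift differed by 0.0186 (SE 0.028) between sites with and without a following A, short of the 2 SE set beforehand as needed, but that bound was too strict, since at this SE it cannot exclude a difference like the 0.05 between the 8-base and 7-base AATATTAA sites, and it differed by 0.0913 (SE 0.0655) between genes with 2 or more sites (0.19 ± 0.06, 27 genes) and with 1 (0.10 ± 0.01, 565 genes), the direction a seed effect would give but within 2 SE. A response of the cells to GATA3 loss was not tested apart from it, since no untransfected cells were analysed here.

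The 15 called lists were tested for both sequences and for the trend of fold change with length and expression. Across genes, Spearman was 0.171 with transcript length and -0.237 with mean CPM, and genes are not independent replicates. Without genes carrying ATATTA or GACGTA 10 of 15 kept their call, and with the trend removed 10 of 15. Each list was therefore tested alone, among genes with a searched 3′ UTR and no site and with the trend fitted without its own members. Brackets hold the adjusted p of camera with the preset correlation, and medians are given ± SE. The SE treat members as independent, and with an estimated correlation 0 lists were called to begin with, so the outcomes below hold only under the preset. Sites as the whole cause are argued against for extravillous trophoblast (-0.16 ± 0.09 to -0.14 ± 0.09, 0.00387), YAP and TAZ (-0.16 ± 0.10 to -0.30 ± 0.15, 3.36e-07), S phase (0.00135), p53 (4.78e-06), cholesterol (0.000278), hypoxia (0.00229) and immediate early and heat shock genes (3.37e-09), and the trend as the whole cause for extravillous trophoblast (-0.16 ± 0.09 to -0.14 ± 0.08, 0.00389), S phase (1.47e-11), p53 (8.78e-07), NF-kB (9.27e-06), YAP and TAZ (0.000872), angiogenic (0.000674), EGF (2.41e-05), hypoxia (0.00243) and immediate early and heat shock genes (0.0311), all of which kept their call, with medians more than 2 SE from 0 except where medians with SE are given, which were within 2 SE before correction too. Sites stay open for NF-kB genes (-0.28 ± 0.10 to -0.17 ± 0.12, 0.00029), which kept their call but with a median that came within 2 SE of 0, and for lists whose call ended with fewer members: matrix (-0.15 ± 0.11 to -0.15 ± 0.14, 0.131), transcription factors (-0.08 ± 0.06 to -0.07 ± 0.22, 0.209), mesenchymal (-0.09 ± 0.08 to -0.09 ± 0.10, 0.0694), EGF (-0.47 ± 0.16 to -0.29 ± 0.39, 0.152), angiogenic (-0.21 ± 0.11 to -0.02 ± 0.17, 0.166) and protease inhibitors (-0.08 ± 0.13 to 0.03 ± 0.15, 0.763), while the 13 mitochondrial genes have no annotated 3′ UTR and were not searched. The trend stays open for cholesterol genes (-0.18 ± 0.05 to -0.10 ± 0.05, 0.00129), likewise, and for transcription factors (-0.09 ± 0.03, 0.069), matrix (-0.17 ± 0.09, 0.0562) and mesenchymal genes (-0.11 ± 0.07, 0.0576), whose medians did not shrink while the calls ended, and protease inhibitors (-0.03 ± 0.10, 0.141), whereas the mitochondrial median went from -0.20 ± 0.02 to 0.01 ± 0.02 (0.9), as the trend alone would give. Whether loss of GATA3 or indirect effects of other targets of the siRNA moved these lists was not tested, since a single siRNA was used per group.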
